A study of Mus musculus with 30 samples.

How the data were processed

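mRNA libraries of the mouse lines HPC7 and HPCLSK were analysed, 18 in all, in 6 groups of 3 (empty vector, STAT3 and STAT3 Y640F in each line). The empty vector is named in the labels after the dsRed marker. Both lines were grown in Iscove's medium with stem cell factor, HPCLSK on agarose-coated plates. The labels give strain 129SV for the HPC7 RNA samples and C57BL/6N for HPCLSK, while the chromatin samples of HPC7 carry C57BL/6N, and they name different library kits in the series text and in the sample protocols. Sequencing was single-end at 50 bp. The series holds 30 samples, and its 12 chromatin samples of HPC7 (9 immunoprecipitations and 3 inputs) were not analysed here.

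The deposited values are counts of reads per gene, raw and not normalized. Per the file headers, the authors counted reads over the exons of each gene with featureCounts 1.5.1 at strand setting 2 on STAR alignments, using GENCODE M13 (GRCm38/mm10), and the labels name Trimmomatic for trimming. All values were whole numbers (0 exceptions). Each library listed 50686 genes. Symbols were matched by gene ID for 50376 of them (45737 with the version and 4639 without it), 310 had no symbol and 136 shared one. Library totals ran from 9537258 to 38556669 counts, so that 3 counts in 1 library correspond to 0.078 to 0.315 CPM. Mitochondrially encoded genes held 1.74 to 3.19% of the counts and the top 10 genes 4.19 to 5.33%. Over 18 pairs of replicate libraries, the chi-square per degree of freedom of the counts ran from 2.76 to 32.32.

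Groups were compared with edgeR 4.0.16 under R 4.3.3: TMM normalization, the filterByExpr filter, and the quasi-likelihood test with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Comparisons within a line used the 9 libraries of the line, with 6 residual degrees of freedom. The empty vector comparison of the lines and the differences of log2 fold changes between the lines used all 18, so CPM quoted there are scaled over 18 libraries. CPM are counts scaled by the TMM-adjusted library total. Errors of log2 fold changes are standard errors, and errors of CPM are standard deviations over 3 libraries. Calls shared by the lines were compared by Fisher's exact test, one-sided for an excess, over genes tested in both, in 12 tests with Benjamini-Hochberg adjustment.

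Before the data were examined, 26 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists cover STAT3 and cytokine-response targets, JAK-STAT components, type I interferon-stimulated genes, antigen presentation and interferon-gamma genes, and stem and progenitor genes. Lineage lists cover granulocytes, monocytes with macrophages and dendritic cells, erythroid cells, megakaryocytes and platelets, mast cells with basophils and eosinophils, B-lymphoid cells, T and natural killer cells, and stromal cells. Further lists hold cell-cycle genes, apoptosis and survival genes, p53 targets, MYC and ribosome-biogenesis genes, glycolysis and hypoxia genes, cholesterol-synthesis genes, and unfolded-protein and amino-acid stress genes. The last hold chemokine, cytokine and NF-kB genes, cytokine receptors, mitochondrially encoded genes, replication-dependent histone genes, immediate-early and heat-shock genes, and sex-linked identity genes. Members called are given over all genes tested and adjusted over the list alone. Lists of at least 5 measured members (25 of 26) had a competitive set test, camera of limma 3.58.1, at its preset correlation of 0.01, with adjustment over the lists of a comparison. Beside it stands the p with a correlation estimated from the libraries.

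Named genes followed this rule. Stat3, Socs3, Pim1, Bcl3 and Cish were named in every comparison. For Y640F against empty vector and against STAT3 in each line, the rule took the 5 called genes with the largest and the 5 with the smallest log2 fold change among genes with an official-style symbol, at least 5 CPM in the higher group and no overlap between the 3 and 3 libraries, which chance gives for 10% of genes. To these it added up to 2 called members of each list, at most 20 such members by size of change. For STAT3 against empty vector and for empty vector between the lines it added up to 1 per list, at most 10 such members. For line differences it took the largest changes alone. Some genes that the rule takes are not reported here. List members outside this rule are examples chosen after their values were seen, as were the genes near 0 in one group.

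Where all libraries of a group were at 0, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio of CPM is given with a 95% exact binomial counting interval. Intervals and floors cover counting error only. With such genes at their bound, 2 of 182 list medians changed, the larger by 0.25 on the log2 scale. Medians per chromosome were taken over tested genes for chromosomes with at least 100 of them, and over 8 blocks of neighbouring genes per chromosome.

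The alternatives were RLE size factors, DESeq2 1.42.0, glmTreat against a fold of 1.5, the adjusted p alone, no low-count filter, at least 5 CPM in 3 libraries, the libraries of the contrast alone, and each library left out in turn. The added alternatives, chosen after seeing the data, left out 2 HPCLSK libraries that stand apart (empty vector replicate 1 and Y640F replicate 1) or removed the median of each chromosome. The procedure was tested on simulated data: at a fold of 2 edgeR recovered 38 to 60% of the changed genes, at 3 it recovered 92 to 100%, at 8 it recovered 100%, and 0 of 20 random lists were called. A fold of 2 is also the minimum for calls, which limits recovery there. The changed genes were drawn from those with a mean of at least 1 CPM, with the spread of these libraries. Recovery of genes below that level was not tested. Simulated genes varied independently, so the random lists do not check the set test where members of a list are correlated. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.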

Results

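RNA was sequenced from 2 mouse haematopoietic stem and progenitor cell lines, HPC7 and HPCLSK, each carrying a retroviral empty vector, a vector for STAT3, or a vector for STAT3 Y640F. STAT3 is a transcription factor activated by cytokine receptors through Janus kinases, and Y640F is a change in its SH2 domain known to activate it. Each of the 6 groups held 3 libraries, 18 in all. Within a line, the comparison with empty vector asks what each form of STAT3 does to the transcriptome. The comparison of the forms asks what the changed residue adds. Stat3 RNA was not equal between the forms in either line, so the residue and the level of Stat3 RNA change together. The HPC7 libraries held 25687081, 23127740 and 34123846 counts with empty vector, 32631109, 37178037 and 29884586 with STAT3, and 29700806, 32553182 and 38556669 with Y640F. The HPCLSK libraries held 13263597, 22154763 and 17069553 counts with empty vector, 12297501, 20996915 and 9537258 with STAT3, and 16228427, 16039935 and 21398768 with Y640F. The series text describes the 3 libraries of a group as technical replicates, so every error and p-value here measures the spread between those libraries and not between separate transductions.

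Stat3 RNA was higher with both vectors in both lines, but the vectors ranked differently by line. In HPC7, Stat3 stood at 227 ± 10.1 CPM (normalized counts, scaled by library total) with empty vector, 1005 ± 22.6 with STAT3 and 684 ± 18.8 with Y640F (SD, n = 3 for each group). In HPCLSK it stood at 348 ± 12.3, 591 ± 41.4 and 1880 ± 44.5 CPM. The log2 fold change against empty vector was 2.15 ± 0.04 (SE; adjusted p = 3.8e-13) for STAT3 and 1.59 ± 0.04 (adjusted p = 1.8e-11) for Y640F in HPC7. In HPCLSK it was 2.43 ± 0.06 (adjusted p = 4.4e-09) for Y640F and 0.76 ± 0.06 (adjusted p = 2.4e-05) for STAT3, the latter under the fold minimum of 2 used for calls. Counts of Stat3 do not separate vector RNA from RNA of the cell's own gene. The gene (ENSMUSG00000004040.16) lies on chromosome 11 at 100885098 to 100939540 of GRCm38.

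Socs3, the feedback inhibitor of JAK-STAT signalling, rose with Y640F in both lines. It went from 3.20 ± 0.395 to 16.0 ± 0.704 CPM in HPC7 (log2 fold change 2.34 ± 0.10, adjusted p = 9.9e-10) and from 28.1 ± 5.81 to 194 ± 21.0 CPM in HPCLSK (2.79 ± 0.14, adjusted p = 1.5e-07). Bcl3, an atypical inhibitor of kappa B family member, rose from 5.75 ± 0.779 to 13.5 ± 1.45 CPM in HPC7 (1.24 ± 0.12, adjusted p = 1.3e-06) and from 19.9 ± 2.58 to 86.5 ± 4.73 CPM in HPCLSK (2.11 ± 0.10, adjusted p = 1.3e-07). The kinase gene Pim1 rose from 108 ± 5.18 to 269 ± 16.1 CPM in HPC7 (1.32 ± 0.05, adjusted p = 3.3e-10). In HPCLSK Pim1 stood at 247 ± 28.3 CPM with empty vector and 464 ± 75.7 with Y640F (0.91 ± 0.11, adjusted p = 5.4e-05), short of the fold minimum. Its log2 fold change was 1.01 without HPCLSK Y640F replicate 1 and 1.11 without HPCLSK empty vector replicate 1 and Y640F replicate 1, the 2 libraries that stand apart from their groups, past the minimum in both.

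STAT3 itself moved these genes differently in the 2 lines. In HPC7 it lowered Pim1 to 51.9 ± 2.01 CPM (log2 fold change −1.06 ± 0.05, adjusted p = 4.4e-09) and Bcl3 to 1.02 ± 0.222 CPM (−2.49 ± 0.17, adjusted p = 8.7e-08). Socs3 was at 1.68 ± 0.171 CPM there, a log2 fold change of −0.91 ± 0.14 (adjusted p = 1.1e-04) that missed the fold minimum and passed it, at −1.02, without HPC7 empty vector replicate 3. In HPCLSK with STAT3, the 3 genes had log2 fold changes of 0.51 ± 0.14 (Socs3, adjusted p = 0.037), 0.36 ± 0.11 (Bcl3, adjusted p = 0.046) and 0.22 ± 0.11 (Pim1, adjusted p = 0.23). The difference of the STAT3 log2 fold changes, HPCLSK minus HPC7, was 2.85 ± 0.21 for Bcl3, 1.41 ± 0.24 for Socs3 and 1.28 ± 0.13 for Pim1 (adjusted p = 1.8e-10, 1.2e-05 and 2.3e-08 over the 5 fixed genes). In the same test Stat3 RNA differed by −1.39 ± 0.07 (adjusted p = 5.6e-13). For these genes the line therefore cannot be told apart from the level of Stat3 RNA. Cish, a target of STAT5, rose in HPC7 with STAT3 (4.54 ± 0.433 to 12.2 ± 0.746 CPM; 1.43 ± 0.10, adjusted p = 1.3e-07) and with Y640F (9.71 ± 0.968 CPM; 1.10 ± 0.11, adjusted p = 1.1e-06). In HPCLSK its log2 fold changes were 0.00 ± 0.14 and −0.41 ± 0.14, neither called. On GRCm38 Socs3 (ENSMUSG00000053113.3) lies on chromosome 11 at 117966079 to 117970047, Pim1 (ENSMUSG00000024014.7) on chromosome 17 at 29490812 to 29496111, Bcl3 (ENSMUSG00000053175.17) on chromosome 7 at 19808462 to 19822770 and Cish (ENSMUSG00000032578.7) on chromosome 9 at 107296026 to 107302784.

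**Figure D1:**
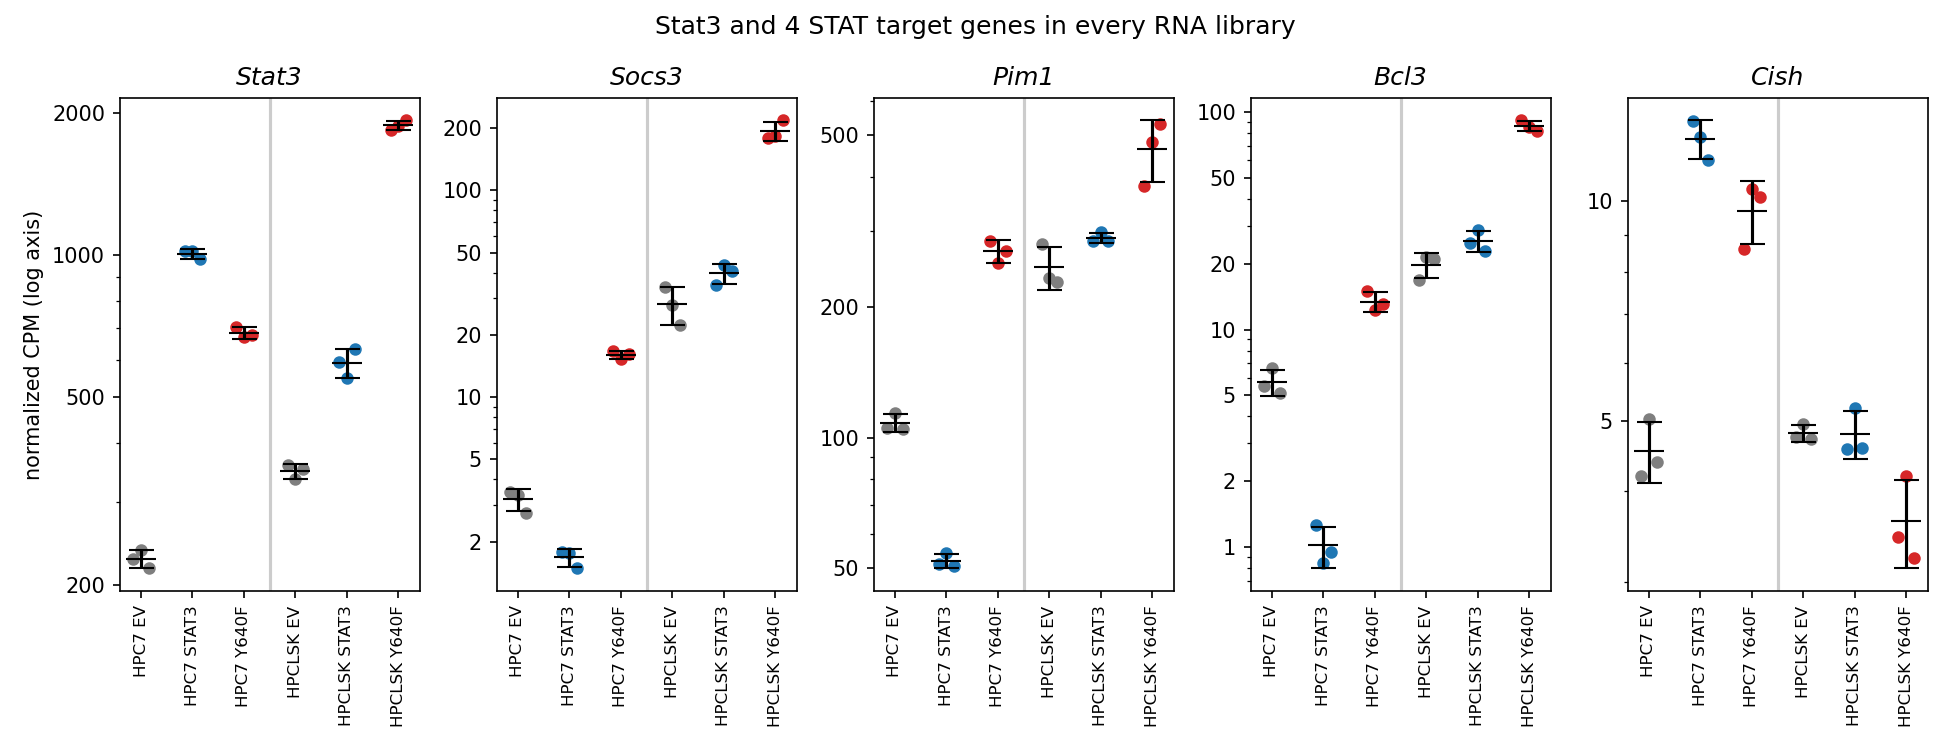
Normalized CPM (log axis) of Stat3, Socs3, Pim1, Bcl3 and Cish in the 6 groups; each dot is a library, and bars give the mean ± SD of 3 libraries. Socs3 and Bcl3 lie highest with Y640F in both lines, and Bcl3 lies lowest with STAT3 in HPC7 at 1.02 CPM.

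In HPC7 cells, STAT3 compared with empty vector lowered 686 genes and raised 230 by a fold of at least 2. Among the lowered were genes of interferon response, antigen presentation and granulocytes. H2-K1, an MHC class I heavy chain, fell from 25.6 ± 5.82 to 0.134 ± 0.0312 CPM (log2 fold change −7.56 ± 0.29, adjusted p = 4.2e-10), and the class I transactivator Nlrc5 fell by 7.14 on the log2 scale. The chemokine receptor gene Cxcr4 fell from 5.32 ± 2.66 to 0.160 ± 0.0858 CPM (−5.00 ± 0.47, adjusted p = 1.2e-06). Nr3c1, the glucocorticoid receptor, had 517 counts over the 3 empty vector libraries and 0 with STAT3, at least 207-fold lower, and Laptm4b had 423 and 0, at least 169-fold lower. With Y640F these 2 genes were near absent as well, at 0.00853 and 0 CPM, against the same empty vector libraries. Among the genes that rose were Muc20 (1.33 ± 0.849 to 15.2 ± 0.237 CPM, 3.45 ± 0.24, adjusted p = 8.9e-08), the pseudokinase gene Prag1 (2.39 ± 0.11) and the VEGF receptor gene Kdr (3.16 ± 0.33).

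By gene list, 13 of 37 measured type I interferon-stimulated genes fell in HPC7 with STAT3, 0 rose and 24 were not called (13 and 0 adjusted over the list alone). The examples are Ifi27l2a (−4.35), Mx2 (−2.13), Bst2 (−1.52) and Isg15 (−1.24). The competitive set test (camera) gave an adjusted p of 2.2e-08 at its preset correlation, and adjusted p = 0.46 with an estimated correlation. Of 24 antigen presentation and interferon-gamma genes, 6 fell and 4 rose (the same counts adjusted over the list alone). Class I genes H2-K1 and H2-D1 (−1.74) and the immunoproteasome gene Psmb8 (−1.34) fell, while class II genes H2-Aa (1.34) and H2-Eb1 (1.29) rose. The set test gave adjusted p = 6.3e-07, and adjusted p = 0.46 with an estimated correlation. H2 genes share sequence, as do Oas and globin genes, so reads may be divided unevenly between their members.

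Granulocyte genes fell as well, 10 of 17 measured against 1 that rose (Ncf1, 1.06), the same counts adjusted over the list alone. Haptoglobin (Hp) fell from 2.73 ± 0.699 to 0.164 ± 0.0736 CPM (−4.02 ± 0.32), and the transcription factor genes Cebpe and Cebpa had log2 fold changes of −1.55 and −1.38. Camera gave adjusted p = 0.0025, and adjusted p = 0.46 with an estimated correlation. Of 17 monocyte, macrophage and dendritic cell genes 6 fell and 2 rose (F13a1, 1.17 ± 0.113 against 0.0503 ± 0.0254 CPM, and Itgax, 1.52), without a set call (adjusted p = 0.17). Of 30 stem and progenitor genes 9 fell and 1 rose (adjusted p = 0.081), with Cd34 at −3.89, the receptor gene Flt3 at −2.57 and Procr at −2.54. Cytokine receptor genes fell in 6 of 28 cases and rose in 2 (set test adjusted p = 0.004, and adjusted p = 0.46 with an estimated correlation). Il10ra went from 265 counts to 1, a ratio of 319 with a 95% counting interval of 56.7 to 12600. In the other direction, 6 of 23 megakaryocyte and platelet genes rose and 0 fell, among them Tubb1 (2.11) and von Willebrand factor (Vwf, 1.78), with a set test adjusted p of 0.039, and adjusted p = 0.46 with an estimated correlation. For that list 3 rose and 1 fell with glmTreat, and 1 of 16 rose with at least 5 CPM in 3 libraries. The counts first given are the same adjusted over each list alone.

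The Y-linked genes Ddx3y, Uty and Eif2s3y all fell in HPC7 with STAT3. Ddx3y went from 119 ± 4.80 to 12.4 ± 0.766 CPM (−3.27 ± 0.06), Uty from 31.1 ± 3.26 to 3.13 ± 0.105 (−3.32 ± 0.10) and Eif2s3y from 58.1 ± 3.42 to 6.98 ± 0.437 (−3.06 ± 0.08). With Y640F they stood at 121, 37.4 and 62.4 CPM. Of the 5 tested genes of the Y chromosome 4 were called lower with STAT3, all between 1010543 and 1286629, and Gm47283, at 90784738 to 90816464, had a log2 fold change of 0.23 ± 0.09 (not called). STAT3 and cytokine-response targets as a list showed no common direction with STAT3 (2 rose, 6 fell, 25 of 33 not called, adjusted p = 0.66), although Vegfa (−2.56 ± 0.52) and Il10 (−2.02) fell beside Bcl3 and Pim1. In total edgeR called 916 of 12683 tested genes, 230 higher and 686 lower, at an adjusted p under 0.05 and a fold of at least 2. The empty vector libraries that both HPC7 vectors are compared with differed from each other, with a chi-square per degree of freedom of 24.11, 14.83 and 12.17 between them against 3.57 to 5.19 within the other HPC7 groups, and 915 to 952 genes were called without any one of them. The split depends on the fold minimum, as the adjusted p alone gave 2956 higher and 3209 lower.

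Y640F in HPC7 raised 576 genes over empty vector and lowered 462. Oas3, an interferon-induced oligoadenylate synthetase, rose from 0.858 ± 0.345 to 31.7 ± 10.0 CPM (log2 fold change 5.22 ± 0.27, adjusted p = 4.0e-09). Csf2rb2, a beta chain of the interleukin-3 receptor, rose from 16.7 ± 2.07 to 98.8 ± 7.81 CPM (2.58 ± 0.09, adjusted p = 1.1e-10), and the stress-induced pseudokinase gene Trib3 from 1.35 ± 0.186 to 18.8 ± 2.06 CPM (3.79 ± 0.16, adjusted p = 4.7e-10). H2-K1 fell to 0.0341 ± 0.0591 CPM (−9.21 ± 0.34, adjusted p = 2.5e-10) and the inflammasome adaptor gene Pycard from 19.8 ± 7.46 to 0.0367 ± 0.0385 CPM (−8.84 ± 0.47, adjusted p = 5.4e-09). Laptm4b and Zfp770 were at 0 counts with Y640F, at least 171-fold and at least 188-fold lower.

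Of 37 interferon-stimulated genes 18 rose and 0 fell with Y640F in HPC7, the same adjusted over the list alone. Oas2 (4.69 ± 0.31), Oasl2 (4.06), Rsad2 (2.94) and Isg15 (2.76) are examples, and Rtp4 had 137 counts against 2, a ratio of 56.4 (counting interval 15.3 to 470). The set test gave adjusted p = 3.2e-11, and adjusted p = 0.48 with an estimated correlation. The Oas genes lie on chromosome 5, whose tested genes had a median log2 fold change of 0.33 in this comparison. Of 33 STAT3 and cytokine-response targets 8 rose and 1 fell (8 and 1 adjusted over the list alone). Besides Socs3, Pim1, Bcl3 and Cish, the risers included Il10 (2.34), Pim2 (1.67) and the survival gene Bcl2l1 (1.01), and Vegfa fell (−1.92). That list's set test gave adjusted p = 9.3e-05, and adjusted p = 0.48 with an estimated correlation.

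Of 26 erythroid genes 14 rose and 3 fell with Y640F in HPC7 (14 and 3 adjusted over the list alone), including the membrane protein gene Epb42 (2.21) and the transcription factor genes Gata1 (1.40) and Klf1 (1.12). The set test did not call this list (adjusted p = 0.21). Aquaporin 1 (Aqp1) went the other way, from 57 counts to 1 (ratio 69.3, counting interval 11.9 to 2780). Granulocyte genes fell in 9 of 17 cases and 1 rose (Mmp9, 1.15), the same adjusted over the list alone. Cebpa, the transcription factor of granulocyte commitment, went from 5.41 ± 2.20 to 0.824 ± 0.0984 CPM (−2.70 ± 0.28), and the granule enzyme gene Mpo fell by 1.87 on the log2 scale. Camera gave adjusted p = 0.0046, and adjusted p = 0.48 with an estimated correlation. Stem and progenitor genes went both ways, 2 of 30 rising (Ly6a, 3.20, and Lmo2, 1.60) and 7 falling, with Hlf from 1.24 ± 0.368 to 0.0477 ± 0.0461 CPM (−4.54 ± 0.50); the set test gave adjusted p = 0.53. Of 15 mast cell, basophil and eosinophil genes 5 rose and 1 fell (adjusted p = 0.036, and adjusted p = 0.83 with an estimated correlation). Of 27 unfolded-protein and amino-acid stress genes, Trib3, Ddit4 (1.70) and Ddit3 (1.59) rose and 0 fell (adjusted p = 0.036, and adjusted p = 0.83 with an estimated correlation). The counts of both lists are the same adjusted over the list alone. In total 1038 of 12683 genes were called, 576 higher and 462 lower.

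Set directly against STAT3 in HPC7, Y640F had 782 genes higher and 219 lower. Ifitm3, an interferon-induced membrane protein, stood at 59.1 ± 10.7 CPM with Y640F and 0.433 ± 0.195 with STAT3 (log2 difference 7.07 ± 0.27, adjusted p = 2.1e-10), and Ifitm1 at 18.5 ± 2.53 and 0.0534 ± 0.0479 (8.41 ± 0.32, adjusted p = 1.9e-10). Csf1, the macrophage colony-stimulating factor, stood at 15.8 ± 0.399 and 1.24 ± 0.137 CPM (3.66 ± 0.19), and the chemokine receptor gene Ccr2 at 33.2 ± 1.30 and 5.60 ± 0.691 CPM (2.57 ± 0.10). Genes lower with Y640F included St7 (0.250 ± 0.155 against 16.0 ± 0.546 CPM, −6.00 ± 0.29), Fam171a1 (−5.07 ± 0.31) and the integrin gene Itga9 (−3.61 ± 0.12).

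Of 37 interferon-stimulated genes 26 were called higher with Y640F than with STAT3 in HPC7 and 0 lower (26 and 0 adjusted over the list alone), with a list median of 2.18. The set test gave adjusted p = 4.1e-37, and adjusted p = 0.17 with an estimated correlation. Oas2 differed by 7.29 ± 0.40, and Oas1a had 274 counts against 1 (ratio 271, counting interval 48.2 to 10700). Antigen presentation genes were higher in 9 of 24 cases and lower in 0 (adjusted p = 5.2e-07, and adjusted p = 0.37 with an estimated correlation), with Nlrc5 at 4.53 ± 0.55 and Tap1 at 1.26. STAT3 and cytokine-response targets were higher in 10 of 33 cases and lower in 2, the cyclin genes Ccnd1 (−1.22) and Ccnd2 (−1.10). Bcl3 (3.72 ± 0.16, adjusted p = 4.8e-10), Socs3 (3.25 ± 0.11, adjusted p = 9.5e-11) and Pim1 (2.37 ± 0.05, adjusted p = 3.4e-12) were among the higher, although Stat3 RNA was lower with Y640F (−0.56 ± 0.04, not called). This list had adjusted p = 7.0e-04, and adjusted p = 0.47 with an estimated correlation. Monocyte genes were higher in 7 of 17 cases and lower in 0 (adjusted p = 0.041, and adjusted p = 0.37 with an estimated correlation), and erythroid genes higher in 13 of 26 and lower in 2 (adjusted p = 0.28). The counts of these 4 lists are the same adjusted over the list alone. In total 1001 of 12683 genes were called, 782 higher and 219 lower (3433 and 3055 with the adjusted p alone).

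In HPC7 the genes of some whole chromosomes lay off 0 together. With Y640F, 89.1% of the 1008 tested genes of chromosome 2 were higher than with empty vector, with a median log2 fold change of 0.47, and 104 of them were called higher against 16 lower. The same chromosome had a median of 0.44 against STAT3. Relative to empty vector, chromosome 1 lay lower with STAT3 and with Y640F (median −0.34 for both) and chromosome 5 higher (0.36 and 0.33), both against the same 3 libraries. In STAT3 libraries the distal block of chromosome 2 (164832873 to 181898712) was higher, at 0.45, and the distal block of the X chromosome (152294828 to 170019281) lower, at −0.49. The distal 3 of 8 blocks of chromosome 19, from 32672563 on, had medians of 0.45, 0.54 and 0.45 with Y640F. The other 15 chromosomes of HPC7 had medians from −0.09 to 0.09 with STAT3 and from −0.08 to 0.01 with Y640F. For Y640F against STAT3 their medians ran from −0.15 to 0.09, the lowest on chromosome 4, where 32.7% of tested genes were higher. In HPCLSK all 20 chromosomes lay between −0.03 and 0.08 with STAT3 and between −0.08 and 0.05 with Y640F. On a scale centred over the 9 HPC7 libraries, chromosome 1 stood at 0.21 ± 0.12 (SD, n = 3) with empty vector, from 0.13 to 0.34 between those libraries, and at −0.11 ± 0.01 with either form of STAT3.

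**Figure D2:**
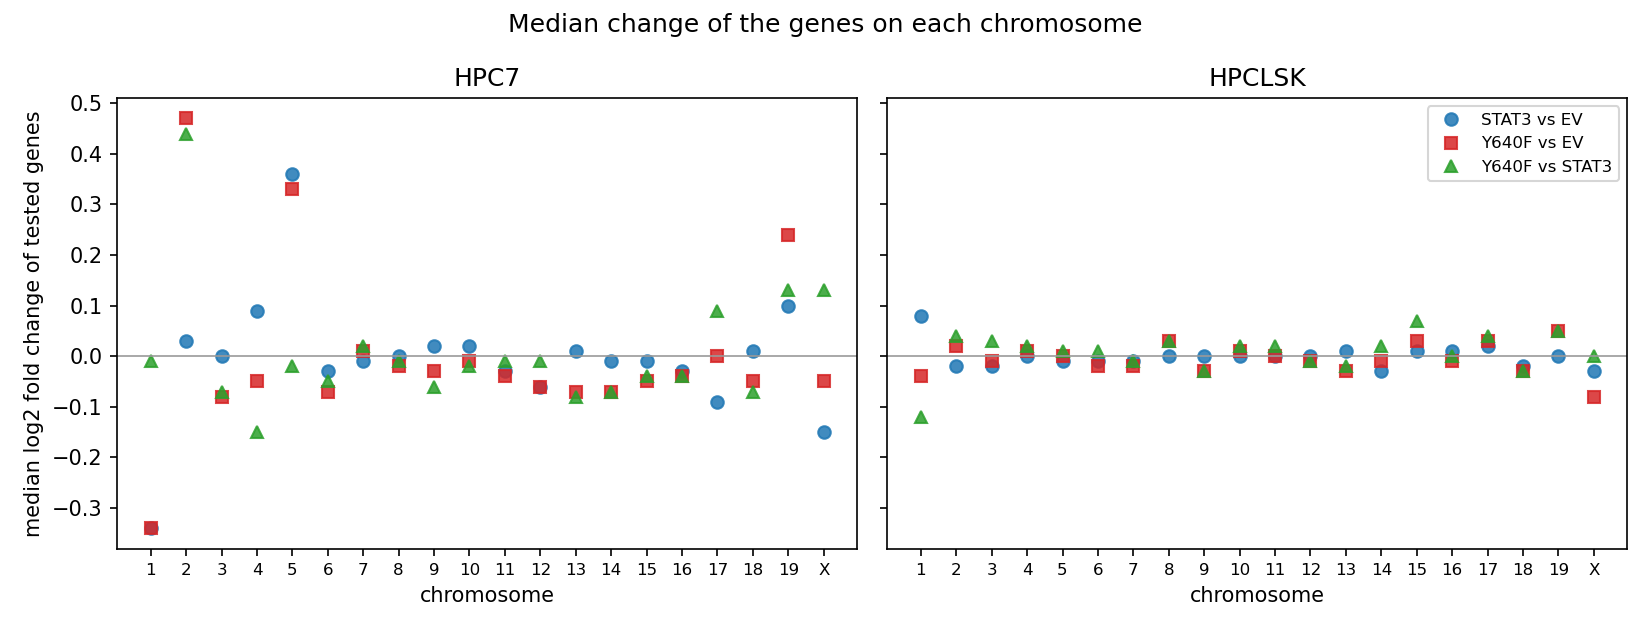
Median log2 fold change of the tested genes of each chromosome (1 to 19 and X) in HPC7 and HPCLSK for the 3 comparisons within a line. In HPC7 chromosome 2 lies at 0.47 with Y640F against empty vector and chromosome 1 at −0.34, while the HPCLSK medians stay between −0.12 and 0.08.

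In HPCLSK cells, STAT3 compared with empty vector raised the neutrophil gene S100a9 and lowered Hoxa9 and the IgE receptor gene Ms4a2. S100a9, a calprotectin subunit, stood at 2367 ± 829 CPM with STAT3 and 284 ± 159 with empty vector (log2 fold change 3.05 ± 0.40, adjusted p = 6.5e-04). The homeobox gene Hoxa9 fell from 142 ± 10.1 to 14.6 ± 0.838 CPM (−3.26 ± 0.19, adjusted p = 5.6e-06), and Ms4a2, the receptor's beta chain, from 899 ± 241 to 108 ± 24.3 CPM (−3.07 ± 0.27, adjusted p = 4.6e-05). Robo1 went from 1146 counts to 2 (ratio 468, counting interval 129 to 3870), and E-cadherin (Cdh1) from 58 counts to 0, at least 15.8-fold lower.

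Of 30 granulocyte genes 14 rose in HPCLSK with STAT3 and 0 fell, and 15 rose adjusted over the list alone. They included S100a8 (3.05), Ngp (2.66), Lcn2 (2.36), Elane (2.35) and Cebpe (1.97). With glmTreat, without empty vector replicate 3 or without STAT3 replicate 1 the count was 9, and 13 rose without empty vector replicate 1 and Y640F replicate 1. Camera gave adjusted p = 2.2e-16, and adjusted p = 0.95 with an estimated correlation. Of 37 STAT3 and cytokine-response targets 5 rose and 0 fell (the same adjusted over the list alone), among them Ccnd1 (1.94), Socs2 (1.79) and the gp130 receptor gene Il6st (1.68). The count was 3 with glmTreat, with at least 5 CPM in 3 libraries, without empty vector replicate 3 or without STAT3 replicate 2, and the set test gave adjusted p = 0.0015, and adjusted p = 0.95 with an estimated correlation. Stem and progenitor genes rose in 2 of 36 cases (Hoxb4, 2.23, and Hoxa10, 1.27) and fell in 6 (adjusted p = 5.9e-04, and adjusted p = 0.99 with an estimated correlation; the same counts adjusted over the list alone). Antigen presentation genes went both ways, with 4 of 29 higher, all class I genes or their activator (H2-Q4, H2-D1, H2-K1 and Nlrc5), and 3 lower, all of the class II pathway (H2-Ab1, H2-DMa and H2-DMb1). The counts were 5 and 3 adjusted over the list alone and the set test gave adjusted p = 0.93. H2-Ab1 went from 7.59 ± 0.272 to 0.292 ± 0.0453 CPM (−4.64 ± 0.23).

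Chemokine, cytokine and NF-kB genes rose in 4 of 28 cases in HPCLSK with STAT3 (Ccl6, Ccl3, Il1b and Ccr1) and 0 fell, the same adjusted over the list alone. The count was 0 with glmTreat, which ends every call of this list, 1 without empty vector replicate 3 or STAT3 replicate 2 and 2 without empty vector replicate 2 or STAT3 replicate 1. The set test gave adjusted p = 0.0043, and adjusted p = 0.99 with an estimated correlation. Of 37 interferon-stimulated genes 2 fell (Oas1a, −1.92, and Oasl2, −1.04) and 4 fell adjusted over the list alone (adjusted p = 5.9e-04, and adjusted p = 0.99 with an estimated correlation). The 2 called over all genes became 6 without empty vector replicate 1 or without the 2 libraries that stand apart, 5 without STAT3 replicate 2, 4 with no low-count filter, and 1 with glmTreat or without any one of the other 4 libraries. In total 577 of 12552 genes were called, 352 higher and 225 lower, the fewest of the 6 comparisons within a line. Libraries in HPCLSK were unequal as well: the chi-square per degree of freedom between replicates was 12.48 and 9.37 for empty vector replicate 1 against its partners and 2.76 between those. It was 25.22 and 32.32 for Y640F replicate 1 against its partners and 3.72 between them. Without these 2 libraries that stand apart, 624 genes were called.

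Y640F in HPCLSK gave the largest count of changed genes within a line, among them chemokine, cytokine and NF-kB, monocyte and granulocyte genes. The collagenase gene Mmp8 rose from 3.67 ± 1.16 to 571 ± 155 CPM (log2 fold change 7.22 ± 0.26, adjusted p = 3.3e-08), and Il6st from 4.35 ± 0.602 to 74.7 ± 9.70 CPM (4.08 ± 0.16, adjusted p = 4.7e-08). The decoy receptor gene Il1r2 rose from 1.53 ± 0.253 to 66.9 ± 8.43 CPM (5.41 ± 0.22, adjusted p = 4.8e-08), and Nos2, the inducible nitric oxide synthase, from 1 count to 319 (ratio 312, counting interval 55.6 to 12400). Osmr, the oncostatin M receptor, was at 0 counts with empty vector and at least 35.2-fold higher with Y640F. The recombinase gene Rag2 was at 0 with Y640F, at least 23.5-fold lower.

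Of 28 chemokine, cytokine and NF-kB genes 23 rose in HPCLSK with Y640F and 1 fell (Il15, −1.26). Cxcl2 (5.04), Il1b (4.42), Ccl3 (4.19) and Tnf (2.94) are examples, and the set test gave adjusted p = 2.5e-12, and adjusted p = 0.38 with an estimated correlation. Of 37 STAT3 and cytokine-response targets 20 rose and 2 fell. Prdm1 (0.0817 ± 0.0713 to 3.58 ± 1.86 CPM, 5.16 ± 0.67), Cebpb (3.11) and Il4ra (3.01) rose, while Ccnd2 (−3.34) and Socs2 (−2.44) fell. Camera gave adjusted p = 3.5e-11, and adjusted p = 0.14 with an estimated correlation. Of 25 immediate-early and heat-shock genes 14 rose and 0 fell, with Klf2 at 3.50 and Egr3 at 3.32 (adjusted p = 4.0e-04, and adjusted p = 0.39 with an estimated correlation). Cytokine receptor genes rose in 11 of 30 cases and fell in 2 (adjusted p = 8.4e-05, and adjusted p = 0.38 with an estimated correlation). These counts are the same adjusted over each list alone. Without the 2 libraries that stand apart, 22 chemokine, cytokine and NF-kB genes, 19 STAT3 targets, 14 immediate-early genes and 10 receptor genes rose.

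Markers of mature myeloid cells were among the genes that rose. Of 24 monocyte, macrophage and dendritic cell genes 16 rose and 0 fell, among them the fractalkine receptor gene Cx3cr1 (3.66 ± 0.583 to 67.8 ± 32.4 CPM, 4.18 ± 0.35), Cd14 (3.88) and Csf1r (3.48). Bst1 rose from 0.174 ± 0.175 to 23.9 ± 8.93 CPM (6.83 ± 0.45). The set test gave adjusted p = 1.3e-06, and adjusted p = 0.38 with an estimated correlation, and 17 rose without the 2 libraries that stand apart. Of 30 granulocyte genes 18 rose, such as S100a8 (4.52) and Lyz2 (3.09), while the secondary granule genes Ngp (−1.40), Camp (−1.96) and Ltf (−2.05) fell. The number that fell was 0 with glmTreat or without empty vector replicate 2, and 1 without Y640F replicate 2. Camera gave adjusted p = 1.3e-06, and adjusted p = 0.39 with an estimated correlation, and 19 rose without the 2 libraries. Some of the risers differed widely between the 3 Y640F libraries, as Scd1 (54.5 ± 44.5 CPM), Il1rn (43.2 ± 38.5) and the eosinophil gene Prg2 (14.7 ± 17.9) show.

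Stem, megakaryocyte and mast cell genes went both ways in HPCLSK with Y640F. Of 36 stem and progenitor genes 10 fell and 4 rose (Hoxb4, Ly6a, Spi1 and Procr), with Hoxa9 at −2.82, Kit at −1.51 and Cd34 at −1.24; the set test gave adjusted p = 0.0038, and adjusted p = 0.54 with an estimated correlation. Of 23 megakaryocyte and platelet genes 9 fell, including Gp5 (−1.81) and Pf4 (−1.42), and 4 rose, including Serpine2 (6.98 ± 0.31) and Vwf (2.79). Here the set test gave adjusted p = 0.023, and adjusted p = 0.54 with an estimated correlation. Mast cell, basophil and eosinophil genes rose in 6 of 21 cases and fell in 7 (adjusted p = 0.65), with Prss34 at 4.40 ± 0.42 and Ms4a2 at −2.97. These 5 lists of lineage genes have the same counts adjusted over the list alone, and without the 2 libraries 9 stem and 8 megakaryocyte genes fell. Interferon-stimulated genes rose in 9 of 37 cases and fell in 2, Usp18 (−1.05) and Rsad2 (−1.47), with a set test adjusted p of 0.12. In total 2032 of 12552 genes were called, 1207 higher and 825 lower, and 1984 were called without the 2 libraries.

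**Figure D3:**
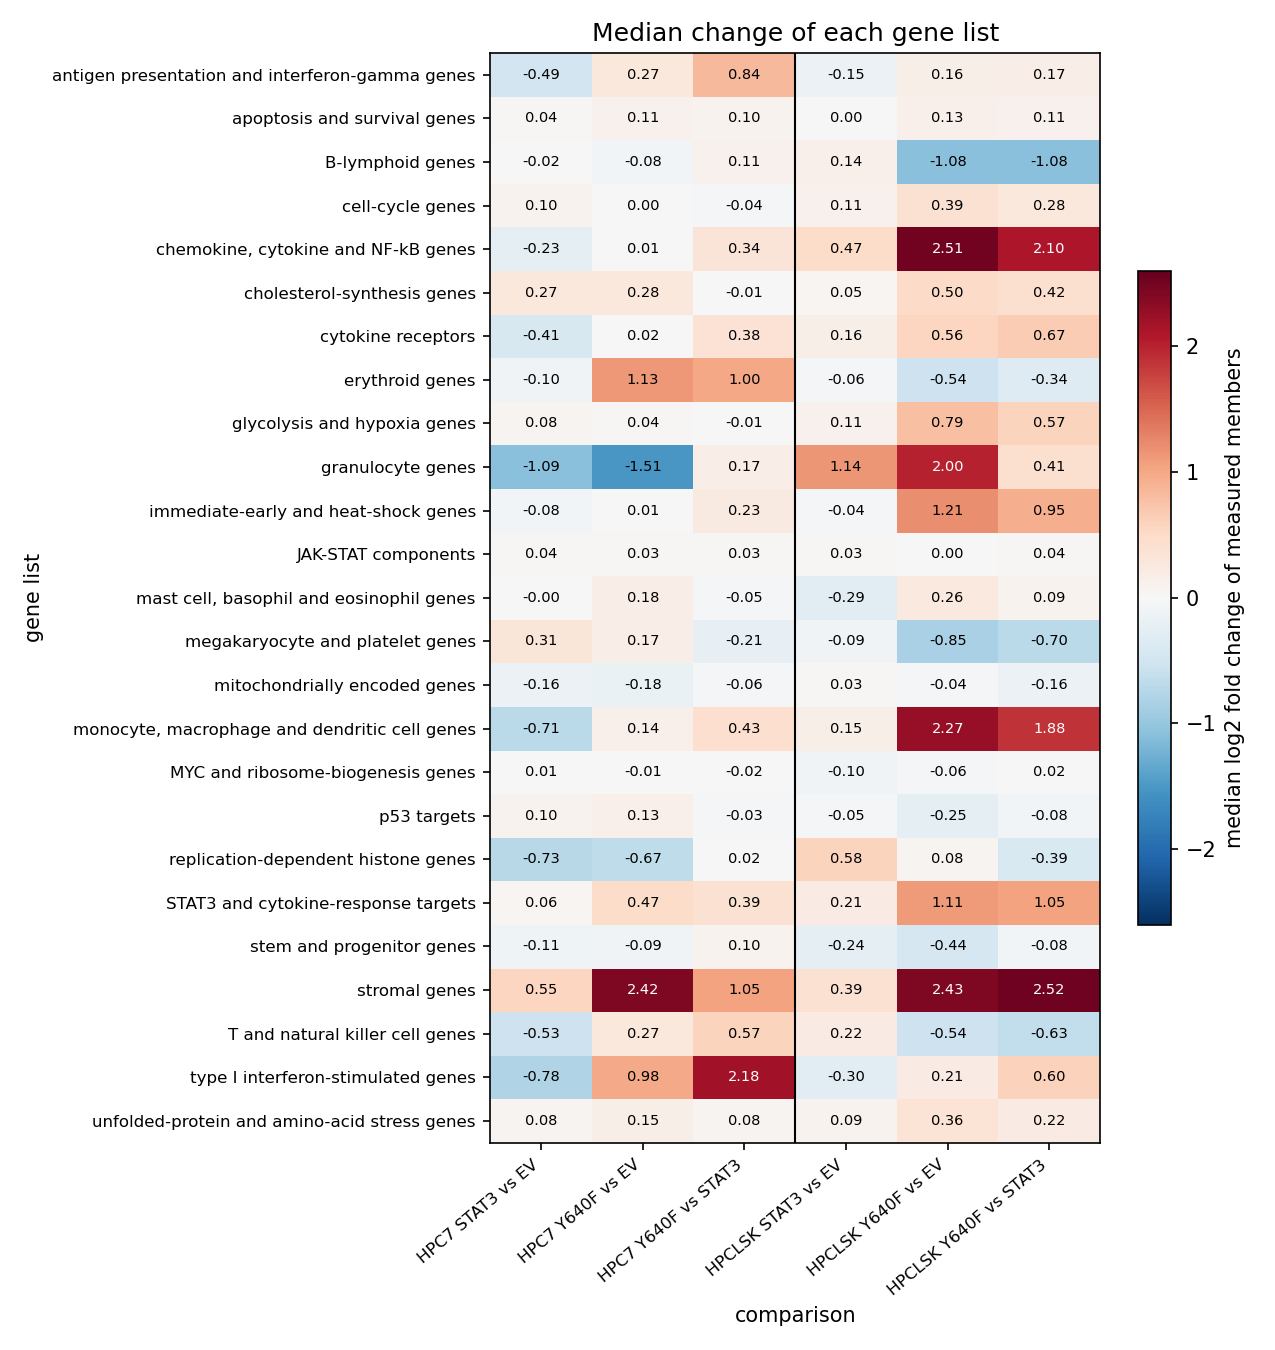
Heat map of the median log2 fold change of the measured members of 25 gene lists (vertical) in the 6 comparisons within a line (horizontal). Chemokine, cytokine and NF-kB genes have a median of 2.51 in HPCLSK with Y640F against empty vector and 0.01 in HPC7, and interferon-stimulated genes 0.21 and 0.98.

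Against STAT3 in HPCLSK, Y640F had 1018 genes higher and 765 lower. Stat3 RNA was also higher with Y640F than with STAT3 there, so the changed residue cannot be told apart from the level of Stat3 RNA. Mmp8 stood at 571 ± 155 CPM with Y640F and 8.12 ± 1.66 with STAT3 (log2 difference 6.14 ± 0.24, adjusted p = 6.9e-08), and the stem cell antigen gene Ly6a at 49.2 ± 3.71 and 1.98 ± 0.317 (4.58 ± 0.16, adjusted p = 5.2e-08). Lactoferrin (Ltf) was lower with Y640F, at 5.23 ± 2.12 against 97.2 ± 46.6 CPM (−4.18 ± 0.60, adjusted p = 2.1e-04), as were Socs2 (−4.24 ± 0.33) and the receptor kinase gene Ephb2 (−6.83 ± 0.27). Rhoj was at 0 counts with STAT3 and at least 264-fold higher with Y640F. Uty stood at 23.8 ± 1.78 CPM with STAT3, 1.35 ± 0.736 with empty vector and 0.267 ± 0.106 with Y640F, while the other 3 measured genes of the sex-linked list were not called in this line.

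Chemokine, cytokine and NF-kB genes were higher with Y640F than with STAT3 in 22 of 28 cases and lower in 1 (adjusted p = 1.1e-10, and adjusted p = 0.36 with an estimated correlation). Monocyte genes were higher in 17 of 24 and lower in 1, Ly6c2 (−2.94), with adjusted p = 4.7e-08, and adjusted p = 0.36 with an estimated correlation. STAT3 and cytokine-response targets were higher in 19 of 37 and lower in 2 (adjusted p = 1.9e-08, and adjusted p = 0.11 with an estimated correlation), with Socs3 at 2.28 ± 0.14 and Bcl3 at 1.75 ± 0.10. Interferon-stimulated genes were higher in 12 of 37 and lower in 1 (adjusted p = 2.4e-04, and adjusted p = 0.49 with an estimated correlation), with Oas2 at 3.34 and Irf7 at 1.98. Granulocyte genes were higher in 12 of 30 and lower in 5, Mpo, Elane, Camp, Ngp and Ltf, without a set call (adjusted p = 0.13). These counts are the same adjusted over each list alone. In total 1783 of 12552 genes were called, 1018 higher and 765 lower, and 1743 were called without the 2 libraries that stand apart. List members quoted as examples outside the rule for named genes were chosen after their values were seen.

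The 2 lines shared part of their response to Y640F. Of 11338 genes tested in both lines, 112 rose over empty vector in both, where 24.3 would be expected if the lines were independent (odds ratio 7.13, one-sided Fisher's exact test, adjusted p = 1.4e-45 over 12 tests), and 76 fell in both (18.7 expected, odds ratio 5.45, adjusted p = 2.2e-26). Against STAT3, 174 were higher with Y640F in both lines (31.3 expected, odds ratio 10.1, adjusted p = 2.8e-86) and 39 lower (7.4 expected, adjusted p = 5.8e-18). Genes that moved in opposite directions were also more than expected at this fold minimum. The excess over independence therefore does not by itself measure a response shared in direction. Over empty vector 78 genes fell in HPC7 and rose in HPCLSK (24.3 expected, adjusted p = 1.4e-20) and 51 did the reverse (18.7 expected, adjusted p = 6.8e-11). Against STAT3 the opposite sets held 60 genes higher in HPC7 and lower in HPCLSK (27.6 expected, adjusted p = 1.2e-08) and 19 of the reverse (8.4 expected, adjusted p = 7.4e-04). With the adjusted p alone and no fold minimum, the 4 opposite sets fell below expectation, for example 786 genes against 959.4.

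With STAT3 the opposite set was the largest. Of the genes that STAT3 lowered in HPC7, 70 were raised in HPCLSK, against 8.5 expected (odds ratio 14.8, adjusted p = 7.1e-46), among them H2-K1, H2-D1, Nlrc5, Il6st, Cebpe, Hp, S100a8 and Ccl3. Of these 70, 32 were also lower with Y640F in HPC7 and 55 also higher with Y640F in HPCLSK. Those calls rest on the same empty vector libraries, so they do not show whether the set is particular to STAT3. Set directly against STAT3 in HPC7, 38 of the 70 were higher with Y640F. In both lines 10 genes rose (2.1 expected, adjusted p = 5.4e-05), 29 fell (6 expected, adjusted p = 1.3e-12) and 5 rose in HPC7 and fell in HPCLSK (1.5 expected, adjusted p = 0.016). With the adjusted p alone, 160 genes rose in both against 184.3 expected (unadjusted p = 0.99), so that this excess reversed, and the 175 higher in HPC7 and lower in HPCLSK were not called (159.9 expected, unadjusted p = 0.086). The 10 became 6 without HPC7 empty vector replicate 3 or HPCLSK empty vector replicate 3, and with at least 5 CPM in 3 libraries the 10 and 29 became 2 and 8. Granulocyte genes hold 4 of the 70.

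The difference between the lines was tested directly as the HPCLSK log2 fold change minus that of HPC7. For Y640F against empty vector, granulocyte genes were higher in this difference in 18 of 30 cases and lower in 0 (median 2.50, set test adjusted p = 2.8e-09, and adjusted p = 0.4 with an estimated correlation). Chemokine, cytokine and NF-kB genes were higher in 21 of 31 and lower in 0 (24 and 1 adjusted over the list alone; adjusted p = 4.1e-09, and adjusted p = 0.4 with an estimated correlation). Monocyte genes were higher in 16 of 25 and lower in 1 (adjusted p = 6.7e-04, and adjusted p = 0.48 with an estimated correlation). Interferon-stimulated genes went the other way, lower in 19 of 40 and higher in 2 (adjusted p = 6.6e-05, and adjusted p = 0.49 with an estimated correlation), as did megakaryocyte genes, lower in 10 of 26 and higher in 2 (adjusted p = 0.0035, and adjusted p = 0.4 with an estimated correlation). Except for the chemokine list, these counts are the same adjusted over the list alone. In the fit of HPC7 alone, only 17 granulocyte, 17 monocyte and 25 chemokine, cytokine and NF-kB genes passed the low-count filter. For the other members of these lists, low counts in HPC7 leave little room to measure a change there. The same limit holds for the line difference of Y640F against STAT3. For H2-K1, HPC7 stood at 25.4 CPM with empty vector and 0.0333 with Y640F and HPCLSK at 475 and 997 CPM (difference 10.25 ± 0.35, adjusted p = 2.8e-13). With STAT3, H2-K1 stood at 0.132 CPM in HPC7 and 1027 in HPCLSK, so its difference is not shown to be particular to Y640F. Of the fixed genes only Cish differed past the threshold (−1.50 ± 0.17, adjusted p = 8.7e-07), while Socs3 had a difference of 0.46 ± 0.20 (adjusted p = 0.057). In total 2082 of 13891 genes differed, 1075 higher in HPCLSK and 1007 lower.

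For Y640F against STAT3, 25 of 40 interferon-stimulated genes had a lower difference in HPCLSK than in HPC7 and 1 a higher one (26 and 1 adjusted over the list alone), with a set test adjusted p of 4.4e-13, and adjusted p = 0.63 with an estimated correlation. Chemokine, cytokine and NF-kB genes were higher in 14 of 31 cases and lower in 0 (adjusted p = 6.1e-04, and adjusted p = 0.71 with an estimated correlation), and antigen presentation genes lower in 8 of 32 and higher in 1 (adjusted p = 0.0087, and adjusted p = 0.63 with an estimated correlation). The counts of both are the same adjusted over the list alone. Granulocyte genes, higher in the difference against empty vector, were here higher in 4 of 30 cases and lower in 2 (median 0.04). Monocyte genes were higher in 7 of 25 and lower in 2 (median 1.07). Neither list had a set call (adjusted p = 0.3 and 0.21). Stat3 differed by 2.24 ± 0.07 (adjusted p = 6.1e-14), Pim1 by −1.67 ± 0.13 (adjusted p = 1.2e-08) and Bcl3 by −1.96 ± 0.20 (adjusted p = 3.5e-07). In total 1734 of 13891 genes differed, 623 higher and 1111 lower (3221 and 3068 with the adjusted p alone). Line, strain label, sequencing run and culture plates changed together, so none of these can be told from the others in any comparison between the lines. The level of Stat3 RNA changed with them, as its difference of 2.24 shows, and cannot be told apart from them either.

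With empty vector alone, the 2 lines already differed in lineage genes. The granule protease gene Ctsg stood at 765 ± 110 CPM in HPCLSK and had 2 counts in HPC7 (ratio 32900, counting interval 9120 to 272000), and the alpha chain of the IgE receptor, Fcer1a, was at 0 in HPC7 and at least 6750-fold higher in HPCLSK. Hoxa9 stood at 144 ± 10.2 CPM in HPCLSK and 0 in HPC7, at least 4000-fold higher. Alpha-fetoprotein (Afp) and the coagulation inhibitor gene Tfpi were at 0 in HPCLSK, at least 580-fold and at least 1770-fold lower. Socs3 was higher in HPCLSK (3.18 ± 0.15, adjusted p = 3.3e-13), as were Bcl3 (1.85 ± 0.13, adjusted p = 8.1e-11) and Pim1 (1.23 ± 0.09, adjusted p = 4.4e-10), while Stat3 (0.66 ± 0.05) and Cish (0.13 ± 0.12) were not called.

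Of 30 granulocyte genes 28 were higher in HPCLSK and 1 lower (median 5.78; adjusted p = 1.3e-09, and adjusted p = 0.38 with an estimated correlation). Mast cell genes were higher in 17 of 25 and lower in 2 (adjusted p = 8.7e-08, and adjusted p = 0.062 with an estimated correlation). Antigen presentation genes were higher in 21 of 32 and lower in 3 (adjusted p = 8.7e-08, and adjusted p = 0.084 with an estimated correlation), and stem and progenitor genes higher in 20 of 36 and lower in 4 (adjusted p = 5.3e-04, and adjusted p = 0.47 with an estimated correlation). Targets of p53 were higher in 12 of 27 and lower in 0 (adjusted p = 7.9e-06), and this was the only list call that held with an estimated correlation (adjusted p = 0.0067). Erythroid genes were lower in 16 of 25 and higher in 5, with a median of −1.97, or −1.96 with members at 0 in a group set to their bound, and no set call (adjusted p = 0.08). MYC and ribosome-biogenesis genes were lower in 8 of 33 and higher in 0 (adjusted p = 2.4e-07, and adjusted p = 0.41 with an estimated correlation). All these counts are the same adjusted over each list alone. In total 5054 of 13891 genes differed, 3163 higher in HPCLSK and 1891 lower (5774 and 5419 with the adjusted p alone).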

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

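The tests chosen after the result was seen are those of library scaling, gene length, blocks of neighbouring genes, X-linked copies, the Y-linked gene that fell least, megakaryocyte genes, lower granulocyte genes, the line difference of STAT3 against empty vector and every value without the 2 HPCLSK libraries that stand apart.

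The results here stand out because the effect of a vector differed between the 2 lines by a direct test of the difference, given as the HPCLSK log2 fold change minus that of HPC7. This held for 2082 genes for Y640F against empty vector and 1734 for Y640F against STAT3. Of 30 drawn regroupings of the libraries, 1 gave as many genes in each case, the real one, and the highest other gave 1501 and 1007. Regroupings that kept the real groups of one line called 504 to 1501 genes (7 drawn) and 616 to 1007 (4 drawn), and those that mixed both lines called 0, so these counts follow the structure of the samples in either line. Because libraries of a group are described as technical replicates, the regroupings do not tell whether chance differences between single transduced cultures gave these counts. For the 6 comparisons within a line and the empty vector comparison, 10 regroupings are too few for a share under 0.05. The real counts of 916, 1038, 1001, 577, 2032, 1783 and 5054 stand against 0 in the highest other regrouping.

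For Y640F against empty vector, the difference was 12.12 for the lysosomal membrane gene Laptm4b, 12.08 for the cyclophilin gene Ppic, 11.52 for Mier2, 10.64 for Prg2 and 10.25 for the class I gene H2-K1. It was −1.50 for Cish, −7.44 for Stk32c, −8.16 for Tmem218, −8.97 for Rab4a and −9.08 for Oaf. In HPC7, counts with empty vector, STAT3 and Y640F were 423, 0 and 0 for Laptm4b and 952, 1 and 1 for Ppic. They were 363, 0 and 0 for Mier2 and 2100, 13 and 4 for H2-K1. In HPCLSK they were 90, 6 and 0 for Tmem218 and 133, 3 and 0 for Rab4a. The differences of these genes are thus not shown to be particular to Y640F. Prg2 in HPCLSK (15, 28 and 687) and Stk32c in HPC7 (28, 34 and 1098) rose mainly with Y640F. Fitted values of genes with a group at 0 depend on the prior count. With a floor of 3 counts over the group, they were 9.51 for Laptm4b, 8.96 for Mier2, 7.88 for Prg2, −4.78 for Tmem218, −5.57 for Rab4a and −6.31 for Oaf, and for Ppic and Stk32c, which had groups at 1 to 3 counts, 10.98 and −6.27. The call of Prg2 was lost without HPC7 empty vector replicate 1 (10.29, adjusted p = 0.074) or replicate 3 (10.66, adjusted p = 0.05), and that of Stk32c without HPCLSK empty vector replicate 1 (−5.26, adjusted p = 0.12) and without the 2 HPCLSK libraries that stand apart (−4.85, adjusted p = 0.17).

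For Y640F against STAT3, the difference was 10.50 for Rhoj, 9.38 for Nos2, 8.61 for the myosin gene Myo1e, 8.21 for Mfap3l, 8.05 for the kinase gene Sgk1 and 2.24 for Stat3. It was −1.67 for Pim1, −1.96 for Bcl3, −6.63 for Tcp11l1, −6.96 for Ephb2, −7.34 for Nat8l and −10.08 for Uty. In HPC7 Uty stood at 30.8 CPM with empty vector, 3.10 with STAT3 and 36.6 with Y640F. In HPCLSK it stood at 1.37, 24.1 and 0.270. The difference of Uty therefore rests largely on the STAT3 libraries, which moved in opposite directions in the lines. Mfap3l stood at 9.84 ± 11.8 CPM in HPCLSK with Y640F (SD, n = 3), and its difference was 6.52 without HPCLSK Y640F replicate 1. With the floor of 3 counts Rhoj was at 6.57, Nos2 at 6.42 and Sgk1 at 6.90. The call of Nos2 was lost without HPC7 STAT3 replicate 3 (7.82, adjusted p = 1). For STAT3 against empty vector the difference was tested for the 5 fixed genes alone and gave −1.39 for Stat3, 1.41 for Socs3, 1.28 for Pim1, 2.85 for Bcl3 and −1.42 for Cish.

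Chromosome-wide shifts in HPC7 are the first pattern weighed. Library scaling would move all chromosomes alike, but genes off chromosomes 1, 2, 5, 19, X and Y had a median of −0.04 with Y640F against empty vector while chromosome 2 stood at 0.47, and gene length is excluded because the smallest difference within a class of length was 0.48. In the same comparison, 160 blocks of neighbouring genes explained 7.93% of the variance of log2 fold changes, against 1.55% in the highest of 100 shuffles and 1.60% in HPCLSK. A change in copy number of chromosomes or segments in the HPC7 cultures is a candidate explanation that these values leave open, with 3 copies in place of 2 giving 0.58 on the log2 scale. Chromosome 1 varied within the empty vector group (0.13 to 0.34), no DNA was measured, and an action of the vectors was not tested separately.

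Y-linked genes in HPC7 STAT3 libraries are the next pattern, with log2 fold changes of −3.27, −3.32 and −3.06 for Ddx3y, Uty and Eif2s3y. Reads reassigned to X-linked copies are excluded for Eif2s3y, since Eif2s3x would have to rise by 1.24 and had a log2 fold change of −0.10 ± 0.07. The same holds for Uty, since Kdm6a would have to rise by 0.38 and had −0.24 ± 0.04. For Ddx3y the values do not decide, since Ddx3x would have to rise by only 0.15 and had −0.01 ± 0.06. Loss of the Y chromosome in most cells may account for these genes, which lie within 1010543 to 1286629, but the fifth tested gene, Gm47283 at 90784738, had a log2 fold change of 0.23 ± 0.09. Whether that gene draws reads from sequence outside the Y chromosome was not tested, so loss of the whole chromosome cannot be told apart from a change limited to the stretch of the other 4. An action of the STAT3 vector, named by the design, was not tested separately.

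Myeloid genes in HPCLSK Y640F libraries are the last. The 2 libraries that stand apart are not the source, since without them 17 monocyte, macrophage and dendritic cell genes were called higher, against 16 with them. A lower share of the main cell type would raise the markers of every other type alike. The megakaryocyte and platelet list had a median of −0.85, but its members went both ways, 9 of 23 called lower and 4 higher. Its set test gave adjusted p = 0.023, and adjusted p = 0.54 with an estimated correlation, so this list does not decide the question. More granulocytes or monocytes in the cultures could account for the rise and cannot be told apart from a change within the cells, since 3 granulocyte list members, Ngp, Camp and Ltf, were called lower beside 18 called higher (0 lower with glmTreat or without empty vector replicate 2). The vector is named by the design, and its action on these genes stays open as a biological explanation that was not tested separately.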

How the results depend on the processing

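The alternatives without the 2 HPCLSK libraries that stand apart and with chromosome medians removed were chosen after seeing the data, and the others were planned. Counts of called genes are given in the order HPC7 STAT3 against empty vector, Y640F against empty vector and Y640F against STAT3, the same 3 for HPCLSK, the line differences of Y640F against empty vector and against STAT3, and empty vector between the lines. With RLE size factors, DESeq2, no low-count filter, glmTreat, the libraries of the contrast alone and chromosome medians removed, all 9 counts of called genes stayed within 1.5 times the reported ones, but some counts of list members did not, as given beside them or here. Without the 2 libraries the last 6 were 624, 1984, 1743, 1941, 1650 and 5290. With at least 5 CPM in 3 libraries, where fewer genes are tested, the counts were 340, 416, 444, 343, 1201, 982, 1418, 1142 and 3089. In HPC7 that filter left 8 granulocyte genes (1 higher and 3 lower with STAT3, 0 and 2 with Y640F), 15 erythroid genes (7 and 2 with Y640F, 8 and 1 against STAT3), and 10 monocyte genes (1 and 3 with STAT3, 3 and 0 against STAT3). With STAT3 it left 25 stem and progenitor genes (1 and 4), 19 cytokine receptors (1 and 1), 29 STAT3 targets (2 and 3) and 17 antigen presentation genes (0 and 5), and with Y640F 7 T and natural killer cell genes (4 and 0) and 2 stromal genes (0). In HPCLSK with Y640F it left 3 B-lymphoid genes (1 and 1) and 3 stromal genes (1 and 0), and no low-count filter gave 4 and 2 of 21 T and natural killer cell genes there and, in HPC7 with Y640F, 5 and 0 of 17 stromal genes. With the adjusted p alone, which drops the fold minimum, the 9 counts of called genes were 6165, 7263, 6488, 1766, 7349, 6756, 6755, 6289 and 11193. Leaving out 1 library at a time gave 915 to 952, 1051 to 1090, 992 to 1018, 480 to 568, 1986 to 2156, 1713 to 1893, 1973 to 2143, 1629 to 1754 and 5123 to 5216.

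Replicate numbers did not pair the libraries: deviations of libraries with the same number correlated from −0.19 to 0.10, and with a replicate block the counts were 923, 1035, 1002, 548, 2019, 1761, 2067, 1714 and 5055, and 1 cell-cycle gene in place of 2 was higher in HPCLSK with Y640F than with STAT3. Genes called higher in both lines with STAT3 were 160 against 184.3 expected with the adjusted p alone (Fisher's exact test, p = 0.99), the reverse of the excess at the fold minimum, and the cause was not tested. Over libraries left out, shared calls numbered 6 to 11 and 25 to 32 (STAT3, higher and lower), 107 to 122 and 72 to 83 (Y640F against empty vector), and 168 to 179 and 35 to 43 (Y640F against STAT3).

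Cish lay near 0 in HPCLSK with STAT3, and its sign turned, at −0.01 with no low-count filter, −0.00 with the replicate block and −0.00 without the 2 libraries, with a range of −0.07 to 0.04 over libraries left out. Its line difference of Y640F against STAT3 ranged from −0.20 to 0.00, and its empty vector difference was −0.00 with chromosome medians removed; none of these was called and the cause was not tested. All 234 values of named genes kept direction and call with DESeq2 and with RLE size factors, as did 1571 values over libraries left out, with 4 calls lost, 4 gained and 4 signs turned. Pim1 in HPC7 with STAT3 stood at −0.97 with chromosome medians removed. The line difference of Socs3 for Y640F against STAT3 passed the fold minimum without HPCLSK STAT3 replicate 1 (−1.04), without HPCLSK Y640F replicate 3 (−1.05) and with chromosome medians removed. With glmTreat, Stat3 in HPCLSK with STAT3 (adjusted p = 0.048), its line difference for Y640F against empty vector (adjusted p = 0.0017) and Pim1 in HPCLSK with Y640F (adjusted p = 0.012) were called, and the line difference of Nos2 was not (adjusted p = 0.091). Of 150 set tests within a line, 44 were called at the preset correlation, and all 44 lost their call with an estimated correlation. The other 106 were called with neither. Depth limits genes near the floor of 3 counts, 0.078 to 0.315 CPM per library.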

Other observations

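The gene lists and their tests were planned, and the tests without the 2 HPCLSK libraries that stand apart and the counts of genes near 0 in one group were chosen after the data were seen.

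A minority of glycolysis, cholesterol-synthesis, stress and cell-cycle genes was called higher in HPCLSK with Y640F against empty vector. Of 31 glycolysis and hypoxia genes 7 rose, including the lactate transporter gene Slc16a3 (log2 fold change 3.64) and the glucose transporter gene Slc2a1 (1.71), and Slc2a3 fell (−1.88). Camera gave this list adjusted p = 0.001, and adjusted p = 0.39 with an estimated correlation; 13 rose and 1 fell with glmTreat, and 4 and 1 without Y640F replicate 1 or without the 2 libraries that stand apart. Of 26 cholesterol-synthesis genes 5 rose, among them Pmvk (1.46) and Fdps (1.31), while 3 rose with the libraries of the contrast alone and 9 without the 2 libraries (adjusted p = 0.025, and adjusted p = 0.74 with an estimated correlation). Of 33 unfolded-protein and amino-acid stress genes 7 rose, such as the cystine transporter gene Slc7a11 (3.85) and Atf3 (3.23), and 8 adjusted over the list alone (adjusted p = 0.0058, and adjusted p = 0.39 with an estimated correlation). Cell-cycle genes rose in 4 of 45 cases, including E2f2 (3.49) and the cyclin gene Ccne1 (1.28), with a list median of 0.39 (adjusted p = 1.3e-06, and adjusted p = 0.38 with an estimated correlation), and in 8 with glmTreat. Against STAT3 in this line, 3 glycolysis and hypoxia, 4 cholesterol-synthesis, 4 stress and 2 cell-cycle genes were higher with Y640F. There, 6 glycolysis and hypoxia genes were higher with glmTreat or without Y640F replicate 3 and 5 without STAT3 replicate 2 or Y640F replicate 2. The 2 cell-cycle genes became 1 with RLE size factors, DESeq2, at least 5 CPM in 3 libraries, the libraries of the contrast alone, or without STAT3 replicate 2, STAT3 replicate 3 or Y640F replicate 1. Apoptosis and survival genes went both ways over empty vector, with 3 of 27 higher, including Fas (2.83) and Casp4 (2.66), and Bcl2 (−1.55) and Tnfrsf10b (−1.71) lower (adjusted p = 0.58), and 5 higher and 3 lower with glmTreat. Of 20 JAK-STAT components 3 rose, the phosphatase genes Ptpn6 (1.53) and Ptpn1 (1.34) and Stat6 (1.10), without a set call (adjusted p = 0.33). The replication-dependent histone list had 1 of 7 lower, Hist1h4i (−1.05, adjusted p = 0.73 for the list), and this count was 0 without empty vector replicate 2 or Y640F replicate 3. Except for the stress list, these counts over empty vector are the same adjusted over the list alone. Mitochondrially encoded genes were lower in HPCLSK than in HPC7 with empty vector in 2 of 9 cases (adjusted p = 0.64).

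Lymphoid and stromal lists had few measured members in either line. In HPCLSK with Y640F against empty vector, 1 of 7 B-lymphoid genes rose, the interleukin-7 receptor gene Il7r (0.482 ± 0.0747 to 9.11 ± 5.97 CPM, SD, n = 3), and 3 fell, or 4 adjusted over the list alone (adjusted p = 0.14). Between the lines with empty vector the B-lymphoid median was 2.65, or 2.40 with members at 0 in a group set to their bound. Of 6 T and natural killer cell genes in HPCLSK, Notch1 (1.79) rose and Nkg7 (−3.28) and Cd28 (−1.20) fell (adjusted p = 0.63). Stromal genes rose in 4 of 6 cases, with fibronectin (Fn1) from 0.0860 ± 0.0852 to 4.08 ± 0.835 CPM (adjusted p = 0.14). In HPC7 with Y640F against empty vector, 5 of 12 T and natural killer cell genes rose, among them Ccl5 (2.53) and Cd4 (1.69), and 3 fell, or 4 adjusted over the list alone (adjusted p = 0.3). Stromal genes rose in 3 of 5 cases there, Sparc (2.74), Kdr (2.64) and Cdh5 (2.42), with adjusted p = 0.014, and adjusted p = 0.48 with an estimated correlation.

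Some genes stood at 5 CPM or more in one group and at 0.1 CPM or less in the other. In HPC7, 11 genes were lost in this sense with STAT3 against empty vector, such as Dbt, Ppic and Zfp462, and 10 with Y640F. Of the 14 genes lost with either vector, 7 were lost with both, Nr3c1 among them. Both counts rest on the same 3 empty vector libraries, so genes lost with both vectors are not evidence of a shared effect. In HPCLSK, 2 were lost with STAT3 (Pik3r6 and Robo1), and with Y640F 13 were gained and 4 lost.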
